A study of Gallus gallus with 9 samples.

How the data were processed

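RNA sequencing of DF-1 chicken fibroblasts was analysed in 9 libraries, 3 in each of 3 groups, and each library's group and replicate number were taken from its title. Per the labels' protocols, RNA was extracted with trizol and polyadenylated RNA was selected with oligo-dT beads, so changes in poly-A tail length or RNA quality can move values, and transcripts without a poly-A tail are under-represented. The authors deposited FPKM values with 2 decimals per gene and library, per the file headers. HISAT2 2.0.5, R 3.4.2, DESeq2 and the genome build GRCg6a are named in the submitters' processing notes, with no role for each; the annotation release and the program that made the FPKM values are not given in the sources used here. FPKM divides by transcript length and by the mapped fragments of the library, so a gene's value also depends on all other genes of that library. The low values were examined, and without gene lengths they gave no relative depth, so the depth is unknown and no counting interval is given.

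The table held 15294 genes with NCBI gene numbers and symbols, 1 line that names no gene, which was left out, and 10 genes at 0 in every library. Of its 94 columns, 82 have no name and were not used; they hold values for 2 genes. No gene position is given there, and the RefSeq gene table at hand is of another assembly, GRCg7b, so no coordinates are printed. That table holds 14265 of the gene numbers and gives another symbol for 903, among the genes named here JAC1 for EDMPN1 and VNN2 for VNN1 and USP41 for USP18. Symbols are printed as the authors' table gives them. Near-identical genes, such as actins, ribosomal proteins and the interleukin-8 family, can share reads, and how those were assigned is not given, so ACTA2, IL8L2 and the ribosomal proteins are less certain. Genes used by every cell, such as GAPDH and TBP, were above 0 in every library.

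Before the data were examined, the groups, tests, alternatives, gene lists and the rule for named genes were fixed. Genes with at least 1 FPKM in at least 3 libraries were tested, 10436 in all. Log2(FPKM + 1) values of all 9 libraries entered 1 fit in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with trend, 6 residual degrees of freedom), with 2-sided tests and Benjamini-Hochberg adjustment per comparison. A gene changed at an adjusted p under 0.05 and changed strongly if the change was also at least 1. The comparisons were 3D_E against 2D, 3D_L against 2D and 3D_L against 3D_E. Gene lists numbered 37, of pathways, complexes and markers of other cell types, with 1059 entries of which 939 were found. Lists with at least 5 tested members, 32 in all, were compared with the other genes by camera with a preset correlation of 0.01 and adjusted over the lists of a comparison.

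Named genes were the 8 with the largest rise and the 8 with the largest fall in each comparison, among strongly changed genes with a symbol, a mean of at least 10 FPKM in the higher group and groups that do not overlap, and up to 4 changed members of each list with the largest change. ACTB, LGALS1, CTSD, GAPDH and TBP fall outside that rule and were chosen after their values were seen. Overlaps between comparisons were set beside 100 draws of simulated unchanged groups and beside independent lists. Alternatives were the pseudocount, the filter, the scaling between libraries, the groups in the fit, the spread model, the replicate number as a block, each library left out, and other list tests. The steps were tested on simulated data of 10436 genes with 100 genes changed by 1 and 100 by 2 on the log2 scale and 1 gene list shifted. These changed genes were drawn only from genes well above the filter in 2D, so the recovery of low genes was not tested. With 1 spread shared by the groups, 87%, 92% and 88% of the changes of 1 were recovered in the order of the comparisons above, and 99%, 96% and 99% of the changes of 2. With each group's own spread, 85%, 84% and 86% of the changes of 1 were recovered, and 34.6%, 1.90% and 35.5% of calls were false, with 1.09%, 0.0392% and 1.09% of unchanged genes called. The pooled spread of the limma fit makes calls that involve 3D_E less certain. Figures were drawn in Python with matplotlib 3.10.9.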

Results

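RNA of DF-1, an immortalised line of chicken embryo fibroblasts, was sequenced in 9 libraries, 3 in each of the groups labelled 2D, 3D_E and 3D_L. The series describes the move of these cells from attached growth to suspension without carriers. The labels do not spell out E and L, so the groups keep their label names here. The numbers are the authors' FPKM values, which scale fragments by transcript length and library size, for 15294 genes. Read counts were not used here, so the depth of each library is unknown. The summed FPKM of a library lay between 641334 and 738281, and between 9826 and 10395 genes reached 1 FPKM. Unless stated otherwise, values are mean FPKM ± SD over the 3 libraries of a group (n = 3). Changes are differences on the log2(FPKM + 1) scale, which understates the change of low genes. For each gene list the members that rose and fell are counted of those tested, and the counts adjusted over the list alone were the same unless given. Nothing in the labels says that the libraries of a group came from separate cultures. The p-values therefore measure only the spread between these libraries, which could be technical.

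The 3 groups lay apart in a principal component analysis of the 10436 genes tested. Component 1 held 73.2% of the variance and placed 3D_L between 2D and 3D_E. Component 2 held 16.4% and set 3D_L (-26.8 to -22.9) apart from both 2D (15.5 to 17.4) and 3D_E (-3.86 to 21.7). Across genes, libraries of 2D and 3D_L correlated at r between 0.957 and 0.962, those of 2D and 3D_E between 0.846 and 0.907, and those of 3D_E and 3D_L between 0.904 and 0.955. Genes are not independent replicates. The libraries of 3D_E stood furthest apart from each other, with a root mean square SD of 0.29 on the log2 scale against 0.12 in 2D and 0.16 in 3D_L. The gene with the highest FPKM was ACTB, cytoplasmic beta-actin, in every library of 2D and 3D_L, and LGALS1, galectin-1, in every library of 3D_E. Ribosomal protein genes held 23.7% ± 0.291 of the summed FPKM in 2D, 22.9% ± 2.79 in 3D_E and 21.3% ± 1.08 in 3D_L. By a 2-sided exact permutation test the share in 2D compared with 3D_E gave p = 0.7 and compared with 3D_L p = 0.1, the smallest p that 3 libraries against 3 can give.

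**Figure D1:**
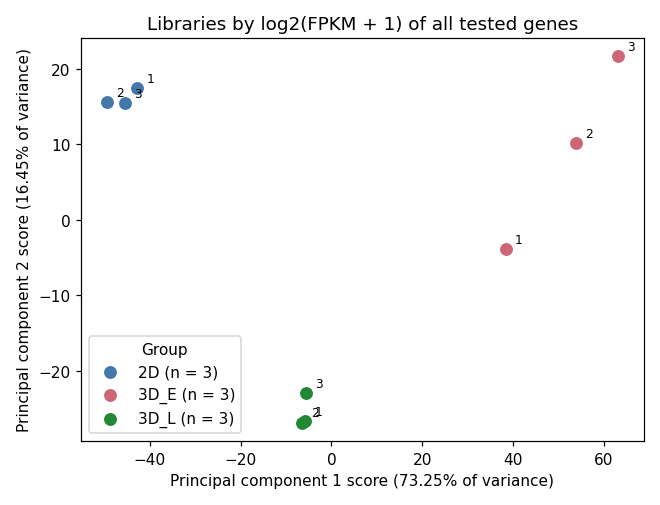
Scores of the 9 libraries on principal components 1 (x axis, 73.2% of the variance) and 2 (y axis, 16.4%) of log2(FPKM + 1), 1 point per library, coloured by group and numbered by replicate. The 3D_E points spread from 38.4 to 63.1 on component 1, while the 3D_L points lie between -6.46 and -5.50.

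The first comparison asks how 3D_E differed from 2D. Most tested genes of mitosis, DNA replication and cholesterol synthesis were lower in 3D_E, and most of those of lysosomes and of inflammation were higher. POSTN (NCBI gene 395429), which encodes the matricellular protein periostin, rose from 0.823 ± 0.158 to 316 ± 55.9 FPKM, a log2 change of 7.43 (limma, adjusted p = 6.11e-10). TSC22D1 (NCBI gene 396005), a transcription regulator, also rose, from 15.8 ± 2.24 to 558 ± 89.1. CALB2 (NCBI gene 396255), the calcium-binding protein calretinin, was listed at 0 in every 2D library and at 249.8 ± 26.1 in 3D_E. FABP7 (NCBI gene 396246), a fatty acid binding protein best known from glial cells, fell from 1857 ± 47.0 to 111 ± 21.9, a log2 change of -4.07 (limma, adjusted p = 1.76e-08). The other genes with the largest rises were CSTA, a cysteine protease inhibitor, GPNMB, EDNRB2, an endothelin receptor, NR4A3 and PAPSS2, with log2 changes between 5.16 and 6.61. The gene listed as EDMPN1 had the largest fall, from 257 ± 18.0 to 7.87 ± 2.06. DCTD, which makes a precursor of thymidine nucleotides, AQP1, a water channel, HMGCS1, LMNB2, SNAI1, a repressor of epithelial genes, and EXO1 fell by between 3.35 and 4.06.

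Among mitosis genes, 0 of 33 rose and 32 fell (camera, adjusted p = 4.46e-18, and adjusted p = 0.0708 with an estimated correlation). Their median log2 change was -2.32. CDK1, the kinase that drives entry into mitosis, fell from 477 ± 18.3 to 47.3 ± 8.14 (limma, adjusted p = 3.71e-08). ANLN, which acts in the cleavage furrow, and the spindle motor KIF11 fell by 3.13 and by 3.05. In the DNA replication list, 0 of 40 rose and 39 fell, 0 and 40 adjusted over the list alone (camera, adjusted p = 1.91e-16, and adjusted p = 0.0117 with an estimated correlation). TK1, thymidine kinase, fell from 139 ± 3.96 to 15.1 ± 5.46. UHRF1, which keeps DNA methylation through replication, fell from 99.0 ± 6.46 to 12.5 ± 1.09, and the clamp loader subunit RFC2 from 125 ± 5.53 to 18.9 ± 2.57. Of the genes for cholesterol synthesis and uptake, 0 of 23 rose and 21 fell (camera, adjusted p = 6.63e-10, and adjusted p = 0.0640 with an estimated correlation). HMGCS1, an early enzyme of that pathway, fell from 143 ± 15.4 to 10.8 ± 3.61. NSDHL and SQLE, which act later in it, fell to 5.26 ± 1.19 and 22.1 ± 4.54 from 59.3 ± 2.38 and 128 ± 3.04. In ribosome biogenesis and MYC, 0 of 30 rose and 25 fell, 0 and 26 adjusted over the list alone (camera, adjusted p = 7.40e-07, and adjusted p = 0.0740 with an estimated correlation). GART, an enzyme of purine synthesis, fell from 49.5 ± 4.57 to 13.2 ± 1.48, and the nucleolar protein NOLC1, from 80.5 ± 2.59 to 29.3 ± 5.56. Within 3D_E, ribosome biogenesis genes differed between replicates 3 and 1 by a median of 0.215 and DNA replication genes by -0.114. Cholesterol genes differed between replicates 3 and 1 by a median of -0.40, against 0.05 for the other genes. Mitosis genes differed by -0.001.

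Attachment and contractile genes fell more often than they rose. Of the integrin and focal adhesion genes, 10 of 34 rose and 22 fell (camera, adjusted p = 0.0348, and adjusted p = 0.606 with an estimated correlation). Quantile normalization ended this call (adjusted p = 0.104). CAV1, the coat protein of caveolae, fell from 361 ± 24.5 to 41.7 ± 25.3 (limma, adjusted p = 1.64e-05), with 70.2, 33.1 and 21.7 in the 3D_E libraries. TES, a protein of focal adhesions, fell from 255 ± 11.99 to 55.7 ± 3.36 and the laminin-binding integrin subunit ITGA3 from 355 ± 38.3 to 86.5 ± 9.33. ITGA8, another integrin subunit, rose from 7.73 ± 0.255 to 37.3 ± 3.01. In the actin cytoskeleton and contractile list, 4 of 24 rose and 16 fell (camera, adjusted p = 0.00615, and adjusted p = 0.235 with an estimated correlation). Its members differed between replicates 3 and 1 of 3D_E by a median of -0.276. The smooth muscle actin ACTA2 fell from 1864 ± 110.3 to 306 ± 119.7 and LMOD1 by 1.74. VIM, the intermediate filament protein vimentin, instead rose from 319.9 ± 11.8 to 2581 ± 419, a log2 change of 3.00 (limma, adjusted p = 4.37e-08). Of matrix proteases and their inhibitors, 9 of 15 rose and 1 fell (camera, adjusted p = 0.0244, and adjusted p = 0.307 with an estimated correlation), with a median of -0.187 between replicates 3 and 1 of 3D_E. The inhibitor TIMP3 stood at 271 ± 118 against 60.8 ± 6.87 and the protease ADAMTS5 at 17.2 ± 4.03 against 3.66 ± 0.275. Without replicate 1 of 3D_E the list was no longer called (adjusted p = 0.0772). Extracellular matrix genes went both ways, 11 rose and 6 fell of 27, and the list was not called (camera, adjusted p = 0.233). The proteoglycan LUM rose from 61.1 ± 3.15 to 537 ± 175 and the collagen COL6A1 from 93.3 ± 9.92 to 332 ± 2.97. COL12A1, a collagen found along fibrils, fell from 13.9 ± 1.58 to 1.34 ± 0.422.

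In the lysosome and autophagy list, 27 of 36 rose and 4 fell (camera, adjusted p = 3.38e-05, and adjusted p = 0.253 with an estimated correlation). Its members differed between replicates 3 and 1 of 3D_E by a median of -0.42. The collagen-degrading protease CTSK rose from 145 ± 19.2 to 1915 ± 534 (limma, adjusted p = 1.86e-07). The protease CTSB rose from 170.0 ± 15.1 to 1392 ± 427, and ULK1, a kinase that starts autophagy, from 1.38 ± 0.252 to 26.3 ± 7.85. Of the inflammatory and NF-kB genes, 17 of 24 rose and 2 fell, 18 and 2 adjusted over the list alone (camera, adjusted p = 0.00206, and adjusted p = 0.106 with an estimated correlation). NFKBIZ, a nuclear regulator of NF-kB, rose from 3.51 ± 0.144 to 65.9 ± 23.7, and the receptor IL1R1 from 0.0900 ± 0.0436 to 10.3 ± 0.552. The hyaluronan-binding TNFAIP6 rose from 9.27 ± 0.707 to 60.01 ± 7.76, and the chemokine CXCL12 fell from 123 ± 3.92 to 14.2 ± 6.90. Of the immediate early genes, 14 of 22 rose and 5 fell (camera, adjusted p = 0.0385, and adjusted p = 0.304 with an estimated correlation). NR4A3, an orphan nuclear receptor, rose from 0.160 ± 0.0458 to 41.8 ± 5.33, and KLF4 and DUSP1 rose as well. The list call was lost without replicate 1 of 3D_E (adjusted p = 0.0786) and with no filter on low values (adjusted p = 0.0731). Of the few chondrogenic and osteogenic markers, 4 of 5 rose and 1 fell (camera, adjusted p = 0.0445, and adjusted p = 0.235 with an estimated correlation). SPP1, osteopontin, stood at 16.9 ± 1.66, COMP at 26.2 ± 2.26 and RUNX2, a regulator of bone formation, at 14.6 ± 0.639 in 3D_E against 0.0700 ± 0.0700, 1.16 ± 0.0351 and 2.13 ± 0.219 in 2D. The call ended without replicate 1 (adjusted p = 0.0786) or replicate 3 of 3D_E (adjusted p = 0.0502). It also ended with a pseudocount of 0.1 (adjusted p = 0.0503) or with no filter (adjusted p = 0.274).

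Chaperone and amino acid genes fell in most cases. In the heat shock list, 4 of 21 rose and 14 fell, 4 and 15 adjusted over the list alone (camera, adjusted p = 0.00917, and adjusted p = 0.235 with an estimated correlation). Between replicates 3 and 1 of 3D_E these genes differed by a median of -0.255. HSP90AA1, the inducible cytosolic chaperone, fell from 1046 ± 126 to 208 ± 95.2 and HSPH1 from 91.6 ± 6.33 to 22.8 ± 1.61. The small heat shock gene HSPB9 rose from 4.90 ± 0.850 to 26.5 ± 11.8. For ATF4 and the amino acid response, 4 of 21 rose and 12 fell (camera, adjusted p = 0.0427, and adjusted p = 0.206 with an estimated correlation). PSAT1 of serine synthesis fell from 56.7 ± 4.94 to 14.2 ± 3.49, and asparagine synthetase ASNS, from 321 ± 29.0 to 98.9 ± 4.33. This list was not called with quantile normalization (adjusted p = 0.101) and without replicate 3 of 3D_E (adjusted p = 0.0502).

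Lists that were not called are given as members that rose and fell of those tested, with the camera adjusted p. The first were basement membrane (2 and 2 of 8, adjusted p = 0.894), YAP and TEAD targets (7 and 6 of 18, 8 and 6 adjusted over the list alone, adjusted p = 0.988) and cell-cell adhesion (5 and 7 of 13, adjusted p = 0.744). Metabolic lists were next, namely fatty acid synthesis and storage (5 and 8 of 19, adjusted p = 0.535), glycolysis (4 and 8 of 20, adjusted p = 0.744) and hypoxia response (6 and 5 of 17, adjusted p = 0.535). Camera also left uncalled nuclear-encoded respiratory chain (10 and 9 of 43, 9 and 9 adjusted over the list alone, adjusted p = 0.952), p53 and cell cycle arrest (13 and 6 of 24, adjusted p = 0.288) and apoptosis (11 and 12 of 28, adjusted p = 0.921). Stress and interferon lists followed, unfolded protein response (3 and 10 of 25, adjusted p = 0.163), oxidative stress and NRF2 (13 and 7 of 27, adjusted p = 0.260) and interferon response (7 and 12 of 30, adjusted p = 0.350). Signals and growth came with TGF-beta and BMP signalling (11 and 4 of 22, 11 and 5 adjusted over the list alone, adjusted p = 0.511), growth factors and receptors (10 and 4 of 19, adjusted p = 0.293) and ribosomal proteins (0 and 9 of 65, 0 and 5 adjusted over the list alone, adjusted p = 0.233). The last were blood and immune cell markers (1 and 1 of 5, adjusted p = 0.831), endothelial and smooth muscle markers (1 and 4 of 7, adjusted p = 0.160) and neural and neural crest markers (4 and 1 of 5, adjusted p = 0.444). Too few members were tested for a list test in myogenic markers (1 and 0 of 1), adipogenic markers (2 and 1 of 3), epithelial markers (2 and 2 of 4) and pluripotency and germ cell markers (0 and 1 of 1). Of the 13 mitochondrially encoded genes, 0 were tested. The cadherin CDH11 rose from 1.84 ± 0.263 to 28.7 ± 7.57, the cell cycle inhibitor CDKN1C from 7.01 ± 0.696 to 30.8 ± 2.82 and the antiproliferative gene BTG2 from 10.4 ± 0.933 to 57.0 ± 5.34. The growth factor TGFB3 fell from 74.9 ± 0.848 to 14.1 ± 3.30 (limma, adjusted p = 3.21e-07). MYOM1, the 1 myogenic marker tested, rose from 4.43 ± 0.271 to 21.5 ± 5.73, and KLF5, listed with pluripotency genes, fell from 6.20 ± 0.492 to 3.52 ± 1.55. Ribosomal protein genes differed between replicates 3 and 1 of 3D_E by a median of 0.53.

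In all, 7116 of 10436 genes changed (68.2%), 3766 higher and 3350 lower in 3D_E (limma, adjusted p under 0.05). Of these, 1420 and 1013 changed by at least 1 on the log2 scale. Camera called 13 of 32 lists, and 1 of them, DNA replication, with an estimated correlation. The fit shared 1 spread among the groups although 3D_E varied more. In simulated data with few changed genes, in which each group kept its own spread, 34.6% of the calls of this comparison were false, against 5.19% with a shared spread. Of the unchanged genes, 1.09% were called with own spreads and 0.108% with a shared spread. The false share of calls depends on how many genes change, so it is not an estimate for the 7116 calls here. The balance turned with quantile normalization (3328 higher and 3576 lower) and with a filter of 5 FPKM (2921 higher and 2994 lower). With a pseudocount of 5 the strongly changed genes numbered 711 higher and 665 lower.

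**Figure D2:**
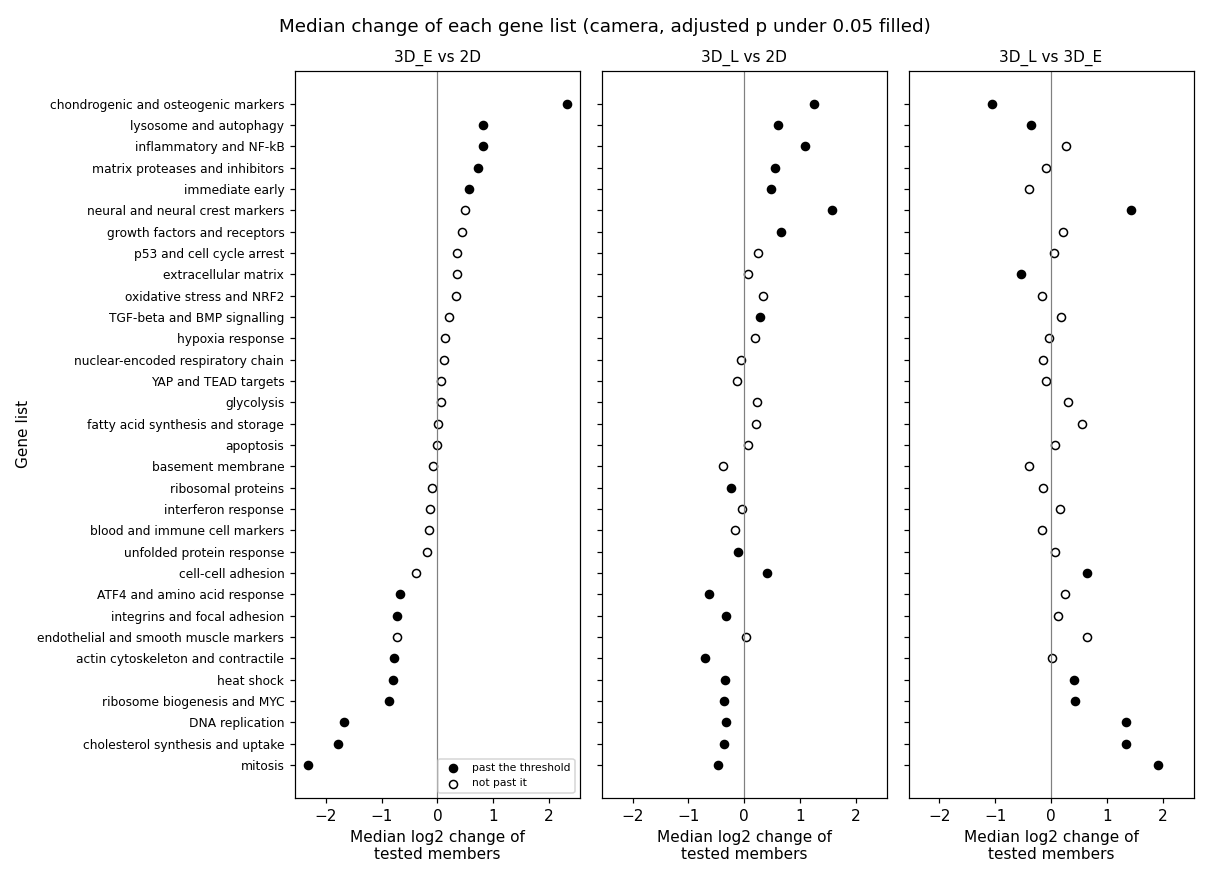
Median log2 change of the tested members of each gene list (x axis, log2(FPKM + 1) units; y axis, the list) in 3 panels, 1 for each comparison, with filled points for camera adjusted p under 0.05 and open points otherwise. Mitosis genes have the lowest median in 3D_E against 2D (-2.32) and the highest in 3D_L against 3D_E (1.91), and the 5 chondrogenic and osteogenic markers have the highest in 3D_E against 2D (2.32).

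The second comparison asks how 3D_L differed from 2D. Most tested inflammatory genes rose, and most contractile and mitosis genes fell. IL8L2 (NCBI gene 396495), a chemokine of the interleukin-8 family, rose from 0.930 ± 0.398 to 132 ± 1.73 FPKM, a log2 change of 6.13 (limma, adjusted p = 1.39e-08). TNFAIP6 (NCBI gene 424315) rose from 9.27 ± 0.707 to 330.3 ± 16.8. ACTA2 (NCBI gene 423787) fell from 1864 ± 110.3 to 298 ± 20.7, a log2 change of -2.64 (limma, adjusted p = 1.46e-05). The other large rises were those of CSTA, from 2.28 ± 0.862 to 212 ± 25.5, LAPTM5, a lysosomal membrane protein, from 0.690 ± 0.191 to 99.6 ± 3.33, GPNMB, EFEMP1, a fibulin of the extracellular matrix, and CYP3A5, a cytochrome P450. CALB2 stood at 101 ± 11.3 against 0 in every 2D library. The largest falls besides ACTA2 were those of COL8A1, a short-chain collagen, LMOD1, MAT1A, BBOX1, TAGLN, IL17REL and PODN, by between 2.18 and 3.10.

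Of the inflammatory and NF-kB genes, 20 of 24 rose and 1 fell (camera, adjusted p = 5.80e-10, and adjusted p = 0.0250 with an estimated correlation). TNFSF15, a cytokine of the tumour necrosis factor family, stood at 10.3 ± 3.11 against 0.05 ± 0.05. The chemokine CX3CL1 stood at 14.7 ± 1.75 against 1.17 ± 0.114 and the colony-stimulating factor CSF3 at 5.57 ± 0.337 against 0.0833 ± 0.0404. In the lysosome and autophagy list, 22 of 36 rose and 2 fell, 24 and 2 adjusted over the list alone (camera, adjusted p = 7.78e-06, and adjusted p = 0.165 with an estimated correlation). CTSB stood at 715 ± 36.0 and CTSK at 529 ± 41.1. For immediate early genes, 11 of 22 rose and 1 fell (camera, adjusted p = 3.94e-04, and adjusted p = 0.118 with an estimated correlation). KLF4, a transcription factor, stood at 16.9 ± 3.49 and NR4A3 at 6.65 ± 0.135. Of growth factors and receptors, 11 of 19 rose and 3 fell, 12 and 3 adjusted over the list alone (camera, adjusted p = 0.00184, and adjusted p = 0.122 with an estimated correlation). IGFBP5, which binds insulin-like growth factors, rose from 7.68 ± 1.18 to 96.2 ± 5.28, and PDGFD, from 75.6 ± 2.499 to 259 ± 17.0, and the receptor MET fell by 1.38. Of matrix proteases and inhibitors, 9 of 15 rose and 2 fell, 12 and 2 adjusted over the list alone (camera, adjusted p = 0.00117, and adjusted p = 0.140 with an estimated correlation). TIMP3 stood at 393 ± 133, MMP9 at 3.29 ± 0.0757 and SERPINE2 at 33.1 ± 2.06 in 3D_L. In TGF-beta and BMP signalling, 8 of 22 rose and 0 fell (camera, adjusted p = 0.0294, and adjusted p = 0.118 with an estimated correlation). ID1, an inhibitor of differentiation factors, rose from 64.8 ± 6.24 to 229 ± 42.1. With a filter of 5 FPKM the list was not called (adjusted p = 0.0518).

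In the actin cytoskeleton and contractile list, 2 of 24 rose and 18 fell, 2 and 19 adjusted over the list alone (camera, adjusted p = 1.65e-07, and adjusted p = 0.0682 with an estimated correlation). TAGLN, the actin-binding protein transgelin, fell from 199.8 ± 11.1 to 38.8 ± 2.47 and LMOD1 from 13.5 ± 0.625 to 0.820 ± 0.226. VIM rose to 1899 ± 106. Of the integrin and focal adhesion genes, 2 of 34 rose and 15 fell, 2 and 17 adjusted over the list alone (camera, adjusted p = 9.73e-04, and adjusted p = 0.328 with an estimated correlation). PDLIM5, a LIM domain protein, fell from 170.0 ± 2.27 to 62.6 ± 0.973, and the integrin subunit ITGB5 rose from 132 ± 7.93 to 378 ± 9.15. Extracellular matrix genes went both ways, 9 rose and 9 fell of 27 (camera, adjusted p = 0.982). The fibrillar collagen COL1A1 fell from 839 ± 162 to 252 ± 3.68. The proteoglycan DCN rose from 164 ± 8.78 to 508 ± 11.6 and POSTN rose to 31.0 ± 1.23. Among cell-cell adhesion genes, 6 of 13 rose and 1 fell, 7 and 1 adjusted over the list alone (camera, adjusted p = 0.0449, and adjusted p = 0.532 with an estimated correlation). CDH11 rose from 1.84 ± 0.263 to 8.19 ± 0.429, and the claudin CLDN11 rose as well. That call was lost without replicate 1 of 2D (adjusted p = 0.0962), without replicate 1 (adjusted p = 0.0640) or 2 of 3D_L (adjusted p = 0.0540). It was also lost under no filter (adjusted p = 0.174), a filter of 5 FPKM (adjusted p = 0.194), TPM (adjusted p = 0.0802) and a fit of only the groups compared (adjusted p = 0.0731).

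Mitosis genes were lower in 3D_L than in 2D, with a median log2 change of -0.46. In that list 0 of 33 rose and 25 fell (camera, adjusted p = 6.85e-09, and adjusted p = 0.118 with an estimated correlation). CDK1 stood at 311 ± 39.1 in 3D_L against 477 ± 18.3 in 2D. RACGAP1, which acts in cell division, fell from 116 ± 8.17 to 69.2 ± 1.83. For DNA replication, 0 of 40 rose and 15 fell, 0 and 16 adjusted over the list alone (camera, adjusted p = 3.11e-06, and adjusted p = 0.0682 with an estimated correlation). TYMS, thymidylate synthase, fell from 98.3 ± 2.53 to 56.5 ± 5.85. Of the cholesterol genes, 0 of 23 rose and 13 fell, 0 and 14 adjusted over the list alone (camera, adjusted p = 3.91e-04, and adjusted p = 0.118 with an estimated correlation). HMGCS1 stood at 81.7 ± 3.90 and LSS at 46.0 ± 0.589 against 78.9 ± 2.39. In ribosome biogenesis and MYC, 0 of 30 rose and 13 fell, 0 and 16 adjusted over the list alone (camera, adjusted p = 2.42e-06, and adjusted p = 0.0711 with an estimated correlation). In the ribosomal protein list, 0 of 65 rose and 5 fell, 0 and 0 adjusted over the list alone (camera, adjusted p = 2.96e-04, and adjusted p = 0.603 with an estimated correlation). The median log2 change of the ribosomal protein genes was -0.24, and replicate 3 of 3D_L differed from replicates 1 and 2 by a median of 0.265 for these genes and 0.249 for respiratory chain genes. RPL5 was at 1336 ± 143 in 3D_L against 1810.2 ± 62.1 in 2D. For ATF4 and the amino acid response, 3 of 21 rose and 13 fell, 4 and 13 adjusted over the list alone (camera, adjusted p = 0.00121, and adjusted p = 0.0684 with an estimated correlation). PSAT1 fell by 1.64.

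Of the unfolded protein response genes, 0 of 25 rose and 7 fell, 0 and 5 adjusted over the list alone (camera, adjusted p = 0.0294, and adjusted p = 0.395 with an estimated correlation). The chaperone HSPA5 fell from 755 ± 40.4 to 552 ± 33.3. The call was lost with a filter of 5 FPKM (adjusted p = 0.0735) and with quantile normalization (adjusted p = 0.143). In the heat shock list, 3 of 21 rose and 8 fell, 3 and 10 adjusted over the list alone (camera, adjusted p = 0.0449, and adjusted p = 0.328 with an estimated correlation). HSPH1, a chaperone, stood at 57.6 ± 1.78 in 3D_L. Leaving out replicate 2 of 2D ended the call (adjusted p = 0.0678), and so did leaving out replicate 1 (adjusted p = 0.0543) or 3 of 3D_L (adjusted p = 0.0532). So did quantile normalization (adjusted p = 0.289), size factors (adjusted p = 0.0504), TPM (adjusted p = 0.0545) and a filter of 5 FPKM (adjusted p = 0.0682). Chondrogenic and osteogenic markers and neural and neural crest markers were also called, each on 5 members. Of the first, 3 rose and 0 fell of 5 (camera, adjusted p = 0.0142, and adjusted p = 0.118 with an estimated correlation), and COMP stood at 6.31 ± 0.903. Of the second, 4 rose and 1 fell of 5 (camera, adjusted p = 0.0159, and adjusted p = 0.318 with an estimated correlation). GAP43, a growth cone protein, stood at 6.12 ± 0.558 and the neurofilament NEFL at 7.05 ± 0.888 against 0.0267 ± 0.0462 and 1.13 ± 0.342. FABP7 was lower, at 572 ± 63.1. With no filter on low values both calls were lost (adjusted p = 0.174 and 0.124).

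Camera did not call the lists below in 3D_L against 2D, given as before with the adjusted p. They began with basement membrane (2 and 2 of 8, 3 and 4 adjusted over the list alone, adjusted p = 0.389), YAP and TEAD targets (2 and 6 of 18, adjusted p = 0.154) and fatty acid synthesis and storage (6 and 4 of 19, 7 and 5 adjusted over the list alone, adjusted p = 0.565). Energy metabolism gave glycolysis (5 and 1 of 20, adjusted p = 0.289), hypoxia response (7 and 2 of 17, adjusted p = 0.288) and nuclear-encoded respiratory chain (2 and 4 of 43, 1 and 3 adjusted over the list alone, adjusted p = 0.151). Next came p53 and cell cycle arrest (9 and 5 of 24, 11 and 7 adjusted over the list alone, adjusted p = 0.346), apoptosis (6 and 4 of 28, adjusted p = 0.766) and oxidative stress and NRF2 (12 and 3 of 27, 14 and 4 adjusted over the list alone, adjusted p = 0.0700). The others were interferon response (4 and 7 of 30, adjusted p = 0.389), blood and immune cell markers (0 and 2 of 5, adjusted p = 0.288) and endothelial and smooth muscle markers (2 and 1 of 7, adjusted p = 0.911). With too few tested members for a list test, myogenic markers (1 and 0 of 1), adipogenic markers (2 and 0 of 3), epithelial markers (2 and 2 of 4) and pluripotency and germ cell markers (1 and 0 of 1) were only counted. Genes in these lists moved all the same. GPX3, a secreted glutathione peroxidase, rose from 23.9 ± 0.445 to 39.4 ± 4.20 and the enolase ENO2 from 4.05 ± 0.687 to 8.98 ± 0.609.

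Of 10436 genes, 3803 changed (36.4%), 2117 higher and 1686 lower in 3D_L (limma, adjusted p under 0.05). Of these, 501 and 133 changed strongly. Camera called 19 of 32 lists, and 1 of them, the inflammatory list, with an estimated correlation. The split moved with the scaling, from 55.7% of calls higher to 44.8% with quantile normalization (1604 higher, 1976 lower) and 66.3% with TPM (2410 and 1225). A fit of only the groups compared called 5783 genes. The count of lower genes was 1106 without replicate 2 of 2D and 1111 without replicate 1 of 3D_L. Strongly changed genes numbered 775 and 202 with a pseudocount of 0.1 and 211 and 57 with 5.

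The last comparison asks how 3D_L differed from 3D_E. Most tested genes of mitosis, DNA replication and cholesterol synthesis were higher in 3D_L. AQP1 (NCBI gene 420384) rose from 37.1 ± 29.0 in 3D_E to 471 ± 60.6 FPKM in 3D_L, a log2 change of 3.88 (limma, adjusted p = 3.61e-05). Its 3D_E libraries had 70.5, 20.8 and 19.9, and its level in 2D was 403 ± 11.1. HAS2 (NCBI gene 395594), which makes hyaluronan, rose from 4.77 ± 0.440 to 42.3 ± 1.86, with 4.68 ± 0.281 in 2D. DKK3 (NCBI gene 396023), a secreted protein of the Dickkopf family, fell from 21.4 ± 1.98 to 0.320 ± 0.135, a log2 change of -4.09 (limma, adjusted p = 1.06e-07), and was 0.157 ± 0.127 in 2D. The other genes with the largest rises were EDMPN1, IL8L2, PAPPA2, a protease that cleaves IGF binding proteins, VNN1, SNAI1 and TNFSF15, by between 2.85 and 4.04. OvoDA1-2, PITHD1, which varied within 3D_E (20.4 ± 13.9), POSTN, DIO2, an enzyme that activates thyroid hormone, WISP2, GEM and PODN had the other largest falls, by between 3.06 and 3.87.

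Of the mitosis genes, 32 of 33 rose and 0 fell, 33 and 0 adjusted over the list alone (camera, adjusted p = 4.03e-22, and adjusted p = 0.0439 with an estimated correlation), and the median log2 change was 1.91. PLK1, a kinase of mitotic progression, rose from 13.9 ± 4.26 to 96.3 ± 0.729 (limma, adjusted p = 1.10e-06). CDK1 rose from 47.3 ± 8.14 to 311 ± 39.1 and ANLN from 15.2 ± 2.67 to 92.8 ± 2.89. In the DNA replication list, 39 of 40 rose and 0 fell, 40 and 0 adjusted over the list alone (camera, adjusted p = 4.38e-19, and adjusted p = 0.00773 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose from 20.6 ± 2.65 to 121 ± 9.81, and the helicase subunit MCM3, from 11.7 ± 1.83 to 63.2 ± 5.24. Of the cholesterol genes, 21 of 23 rose and 0 fell (camera, adjusted p = 2.11e-11, and adjusted p = 0.0439 with an estimated correlation). HMGCS1 rose by 2.85, NSDHL by 2.73 and SQLE by 2.31. In ribosome biogenesis and MYC, 19 of 30 rose and 0 fell (camera, adjusted p = 3.98e-04, and adjusted p = 0.229 with an estimated correlation). PAICS of purine synthesis stood at 108 ± 3.21 against 45.1 ± 12.7.

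Of lysosome and autophagy genes, 1 of 36 rose and 19 fell (camera, adjusted p = 0.00136, and adjusted p = 0.547 with an estimated correlation). The medians of replicate 3 minus replicate 1 of 3D_E were -0.420 for this list, -0.346 for cell-cell adhesion, -0.306 for neural markers, -0.255 for heat shock and -0.165 for extracellular matrix genes. CTSK fell from 1915 ± 534 to 529 ± 41.1, and TPP1, a lysosomal peptidase, from 242 ± 57.0 to 76.9 ± 6.45. ULK1 fell by 1.87, whereas the protease CTSC rose from 152 ± 35.0 to 352 ± 20.3. Of the extracellular matrix genes, 4 of 27 rose and 16 fell, 5 and 16 adjusted over the list alone (camera, adjusted p = 0.0380, and adjusted p = 0.639 with an estimated correlation). The fibrillin FBN2 fell from 24.1 ± 4.41 to 6.58 ± 0.377, and LUM fell as well. The call was lost without replicate 1 of 3D_E (adjusted p = 0.0999) and without replicate 3 of 3D_L (adjusted p = 0.0596). Among heat shock genes, 12 of 21 rose and 4 fell (camera, adjusted p = 0.0463, and adjusted p = 0.547 with an estimated correlation). HSP90AA1 rose from 208 ± 95.2 to 694 ± 47.3 and the small chaperone HSPB1 fell from 545 ± 181 to 218 ± 34.5. Among cell-cell adhesion genes, 10 of 13 rose and 2 fell (camera, adjusted p = 0.0463, and adjusted p = 0.674 with an estimated correlation). N-cadherin, CDH2, rose from 125 ± 46.0 to 346 ± 25.8. Of chondrogenic and osteogenic markers, 1 rose and 4 fell of 5 (camera, adjusted p = 0.0463, and adjusted p = 0.324 with an estimated correlation), and SPP1 stood at 3.21 ± 0.854. Of neural and neural crest markers, 3 rose and 0 fell of 5 (camera, adjusted p = 0.0463, and adjusted p = 0.580 with an estimated correlation). GAP43 stood at 6.12 ± 0.558 against 0.377 ± 0.218. Without replicate 1 of 3D_E the heat shock (adjusted p = 0.0581) and chondrogenic lists (adjusted p = 0.0985) were not called. Without replicate 3 of 3D_E that held for cell-cell adhesion (adjusted p = 0.0697), heat shock (adjusted p = 0.0697), chondrogenic (adjusted p = 0.0617) and neural markers (adjusted p = 0.118). Leaving out replicate 1 of 3D_L ended the call of cell-cell adhesion (adjusted p = 0.0511). With quantile normalization the calls of cell-cell adhesion (adjusted p = 0.0714), heat shock (adjusted p = 0.0804) and chondrogenic markers (adjusted p = 0.0665) ended. TPM ended those of cell-cell adhesion (adjusted p = 0.0553), heat shock (adjusted p = 0.0556) and neural markers (adjusted p = 0.0534). With a pseudocount of 0.1 these 4 calls also ended (adjusted p = 0.0572, 0.0572, 0.0698 and 0.0698). No filter on low values ended those of cell-cell adhesion, chondrogenic and neural markers (adjusted p = 0.0638, 0.297 and 0.130). A filter of 5 FPKM ended those of cell-cell adhesion and heat shock (adjusted p = 0.153 and 0.0935), and a fit of only the groups compared that of heat shock (adjusted p = 0.0506).

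Single genes outside the called lists moved as well. CAV1 rose from 41.7 ± 25.3 to 265 ± 37.4, the integrin subunit ITGA6 from 59.9 ± 18.7 to 168 ± 22.2, TGFB3 from 14.1 ± 3.30 to 83.7 ± 3.71 and CSF3 from 0.273 ± 0.0643 to 5.57 ± 0.337. ACTA2 stood at 306 ± 119.7 in 3D_E and 298 ± 20.7 in 3D_L, with a log2 difference of 0.02 (limma, adjusted p = 0.931). Lists that camera did not call follow, with the adjusted p. Surface and skeleton lists were basement membrane (2 and 4 of 8, adjusted p = 0.444), integrins and focal adhesion (14 and 9 of 34, adjusted p = 0.444) and actin cytoskeleton and contractile (4 and 9 of 24, adjusted p = 0.444). The next were YAP and TEAD targets (4 and 7 of 18, adjusted p = 0.444), matrix proteases and inhibitors (3 and 6 of 15, adjusted p = 0.444) and fatty acid synthesis and storage (10 and 4 of 19, adjusted p = 0.192). Oxygen and energy gave glycolysis (8 and 5 of 20, 10 and 5 adjusted over the list alone, adjusted p = 0.301), hypoxia response (4 and 5 of 17, adjusted p = 0.958) and nuclear-encoded respiratory chain (6 and 11 of 43, 6 and 8 adjusted over the list alone, adjusted p = 0.310). Then came p53 and cell cycle arrest (3 and 11 of 24, 4 and 11 adjusted over the list alone, adjusted p = 0.364), apoptosis (10 and 10 of 28, adjusted p = 0.909) and unfolded protein response (9 and 6 of 25, adjusted p = 0.460). Not called either were ATF4 and amino acid response (6 and 6 of 21, 7 and 6 adjusted over the list alone, adjusted p = 0.470), oxidative stress and NRF2 (8 and 10 of 27, 8 and 12 adjusted over the list alone, adjusted p = 0.444) and interferon response (11 and 7 of 30, adjusted p = 0.444). The same held for inflammatory and NF-kB (12 and 8 of 24, adjusted p = 0.162), TGF-beta and BMP signalling (7 and 6 of 22, adjusted p = 0.502) and growth factors and receptors (7 and 5 of 19, adjusted p = 0.444). It also held for immediate early (5 and 11 of 22, 5 and 12 adjusted over the list alone, adjusted p = 0.162) and ribosomal proteins (3 and 3 of 65, 0 and 0 adjusted over the list alone, adjusted p = 0.295). Last came blood and immune cell markers (0 and 1 of 5, adjusted p = 0.444) and endothelial and smooth muscle markers (4 and 2 of 7, adjusted p = 0.444). Too few members for a list test remained in myogenic markers (0 and 0 of 1), adipogenic markers (1 and 0 of 3), epithelial markers (1 and 0 of 4) and pluripotency and germ cell markers (1 and 0 of 1).

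Between 3D_L and 3D_E, 5591 of 10436 genes changed (53.6%), 2841 higher and 2750 lower in 3D_L (limma, adjusted p under 0.05). Of these, 605 and 561 changed strongly. Camera called 10 of 32 lists, and with an estimated correlation 3, mitosis, DNA replication and cholesterol synthesis. In simulated data with few changed genes and own spreads, 35.5% of the calls of this comparison were false, against 6.07% with a shared spread. Of the unchanged genes, 1.09% were called with own spreads and 0.127% with a shared spread. The false share of calls depends on how many genes change, so it is not an estimate for the 5591 calls here. Without replicate 1 of 3D_E 865 genes were strongly lower, without replicate 3 of 3D_E 6 lists were called. Lower genes outnumbered higher ones with size factors (2709 higher and 2903 lower), quantile normalization (2764 higher and 2840 lower), no filter on low values (2970 higher and 3109 lower) and without replicate 1 of 3D_E (3443 higher and 3604 lower). With a pseudocount of 5 the strongly changed genes numbered 359 and 254.

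Genes were then followed from 2D through 3D_E to 3D_L, an order that the labels do not state. Words such as back and further describe levels in that assumed order only. TSC22D1, CTSB and SQSTM1, an autophagy receptor, were higher in both 3D groups than in 2D, and ACTA2, TAGLN and PSAT1 were lower in both. SQSTM1 stood at 75.1 ± 2.37 in 2D, 861 ± 95.9 in 3D_E and 608 ± 33.8 in 3D_L. Of the genes changed in 3D_E, 4670 changed back in 3D_L. They were 2370 up and then down, such as CTSK and POSTN, and 2300 down and then up, such as CDK1 and HMGCS1. Of these, 2840 were not called in 3D_L against 2D, among them CAV1 and TGFB3, and 1746 were still called in the direction of 3D_E. A gene not called need not be back at its 2D level. The shared fit called 3803 genes in 3D_L against 2D, and a fit of only the groups compared called 5783. The count that changed back lay between 3580 and 5987 when single libraries were left out. A further 170 moved further the same way, 126 up, such as TNFAIP6 and IL8L2, and 44 down, such as TAGLN and LMOD1. Another 751 were called between 3D_E and 3D_L and not in 3D_E against 2D, 415 up, such as HAS2, and 336 down (479 in all without replicate 2 of 3D_L). Simulated unchanged groups gave a mean of 7.5 genes that changed back and at most 23, and independent lists of these sizes would share 1904. Independent lists leave out that both comparisons use the 3D_E libraries, and the simulated groups held no changed genes. How far the spread of 3D_E raises the count among genes that did change was not simulated. Across genes the correlation of the 3D_E minus 2D and 3D_L minus 3D_E changes was -0.817, against -0.817 in simulated unchanged groups, since 3D_E enters both with opposite sign. The covariance was -0.521 against -0.0281.

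Against 2D, 3185 genes changed in the same direction in both 3D groups, 1746 higher, such as CSTA and GPNMB, and 1439 lower, such as ACTA2 and MAT1A. In opposite directions 84 genes changed. Independent lists of these sizes would share 764 and 541 genes by direction and 1288 in opposite directions. Simulated unchanged groups shared at most 1. Across genes the log2 changes correlated at r = 0.731, with 0.237 (0.189 to 0.269) in simulated unchanged groups. Their covariance was 0.393 against a simulated 0.00484, a difference of 0.389. Both comparisons used the same 3 libraries of 2D, too few to split. The simulated groups shared their 2D libraries in the same way and gave covariances of 0.00377 to 0.00553. Shared controls therefore account for little of the observed covariance. How far they raise the count of shared genes among genes that did change was not simulated. The count in opposite directions was 147 in fits of only the groups compared and 268 without replicate 1 of 3D_E. It was 49 without replicate 2 of 3D_E, 54 without replicate 1 of 3D_L, and 46, 42 and 43 without replicates 1, 2 and 3 of 2D.

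**Figure D3:**
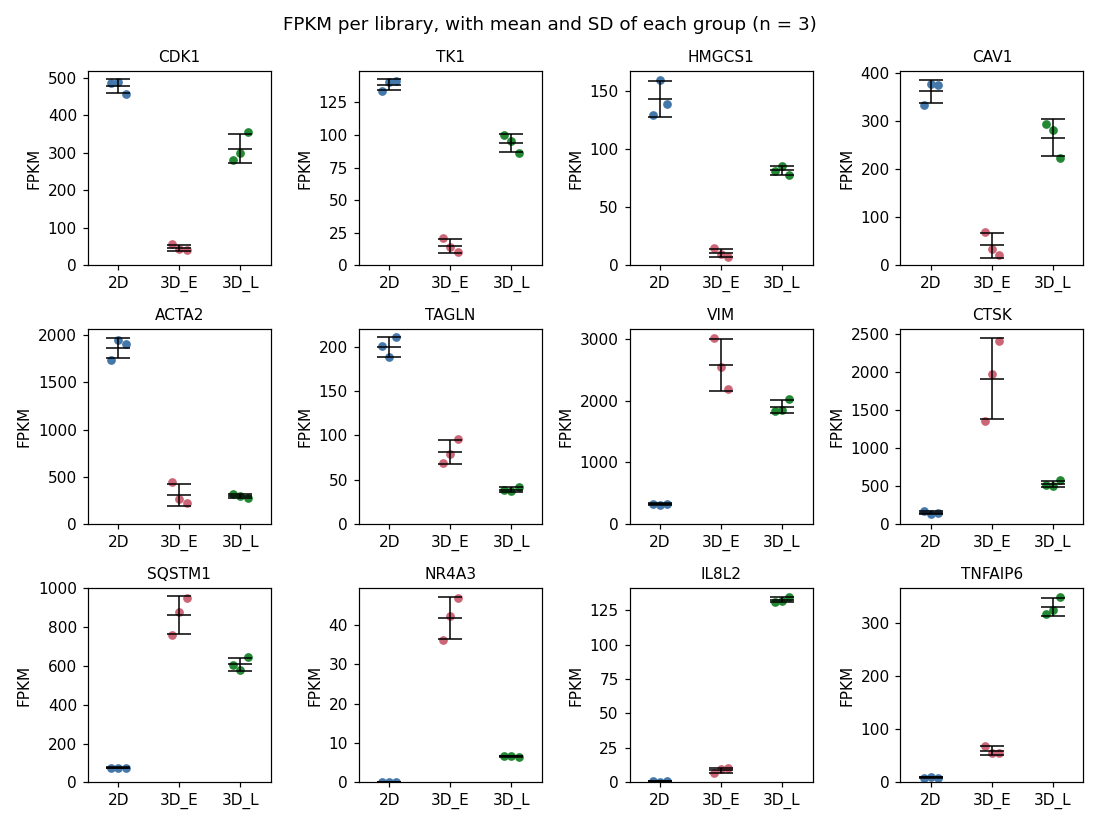
FPKM of 12 named genes (y axis, linear, from 0) in the libraries of 2D, 3D_E and 3D_L (x axis), 1 point per library, with horizontal lines at the mean and at 1 SD either side (n = 3). CDK1 has its lowest values in 3D_E (47.3 ± 8.14) and IL8L2 its highest in 3D_L (132 ± 1.73).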

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

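The genes below changed in opposite directions against 2D in the 3D groups and were picked for these results. Among them, both calls against 2D were tried under the other settings only for CDH5 and KLF5. The fit shared 1 spread among the groups although 3D_E varied more, so the calls of 3D_E against 2D are less certain. That holds above all where the 3D_E libraries varied widely for the size of the change, as for MYL9, SPRY4, KLF5, CTSC and USP18. The count of all genes that changed in opposite directions, 84 here, lay between 42 and 268 when single libraries were left out. The comparison of 3D_L with 3D_E was planned, but its p-values add no independent support for genes picked in this way. PODN, a leucine-rich matrix protein, had 29.8 ± 1.67 in 2D, 55.6 ± 5.48 in 3D_E and 5.78 ± 0.137 in 3D_L, a log2 difference of -3.06 between the 3D groups (limma, adjusted p = 1.06e-07). WISP2, a matricellular protein, had 49.3 ± 6.81 in 2D, 197 ± 29.1 in 3D_E and 19.6 ± 0.559 in 3D_L, a difference of -3.25 (limma, adjusted p = 1.73e-07). IL17REL, a relative of interleukin-17 receptors, stood at 133 ± 6.41 in 2D, 181 ± 20.4 in 3D_E and 25.8 ± 1.68 in 3D_L, a difference of -2.76. FHL1, a LIM domain protein of muscle and fibroblasts, stood at 2.13 ± 0.248 in 2D, 13.3 ± 1.49 in 3D_E and 1.27 ± 0.210 in 3D_L, a difference of -2.66. For MYL9, a regulatory myosin light chain, the levels were 309.8 ± 23.3 in 2D, 430.0 ± 86.2 in 3D_E and 204 ± 15.8 in 3D_L, a difference of -1.06 (limma, adjusted p = 2.65e-04).

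The other genes were lower in 3D_E and higher in 3D_L than in 2D. CDH5, the cadherin of endothelial cells, had 6.79 ± 0.113 in 2D, 1.51 ± 0.393 in 3D_E and 9.83 ± 0.297 in 3D_L, a log2 difference of 2.12 (limma, adjusted p = 6.19e-07). Its rise in 3D_L over 2D was not called with quantile normalization (adjusted p = 0.0950). DUSP4, a phosphatase of MAP kinases, stood at 12.2 ± 1.38 in 2D, 3.25 ± 0.524 in 3D_E and 16.7 ± 0.693 in 3D_L, a difference of 2.06. SPRY4, an inhibitor of growth factor signalling, stood at 5.26 ± 0.542 in 2D, 3.02 ± 1.49 in 3D_E and 13.5 ± 3.27 in 3D_L, a difference of 1.90. The transcription factor KLF5 had 6.20 ± 0.492 in 2D, 3.52 ± 1.55 in 3D_E and 10.9 ± 1.14 in 3D_L, a difference of 1.45. Its rise over 2D (limma, adjusted p = 0.0239) was lost with quantile normalization and without replicates 2 and 3 of 2D or 1 and 2 of 3D_L, with adjusted p of up to 0.0875. CTSC, a lysosomal peptidase, stood at 198 ± 9.20 in 2D, 152 ± 35.0 in 3D_E and 352 ± 20.3 in 3D_L, a difference of 1.23. USP18, a protease of the interferon response, stood at 26.0 ± 1.08 in 2D, 20.4 ± 3.68 in 3D_E and 35.0 ± 2.00 in 3D_L, a difference of 0.77 (limma, adjusted p = 8.24e-04).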

How the results depend on the processing

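Array weights were added after the data were seen. No call of a named gene or list reversed, and 394 of 427 calls of named genes and 26 of 42 calls of lists held under every scaling, filter, fit and left-out library tried. The named genes were picked from the same data, mostly for large changes, so their share does not describe calls in general. The cause of the changes below was not tested. With a pseudocount of 0.1, 775 and 202 genes were strongly higher and lower in 3D_L than in 2D, the correlation of the changes against 2D was 0.756 (0.694 with quantile normalization) and 6 lists were called between the 3D groups. With a pseudocount of 5, strongly higher and lower genes numbered 711 and 665 in 3D_E against 2D, 211 and 57 in 3D_L against 2D and 359 and 254 between the 3D groups. Fitting only the groups compared called 5783 genes in 3D_L against 2D, 2630 lower, and 147 in opposite directions, and array weights per group 5839 (3179 and 2660) and 147; weights per library did not converge and gave no usable value. In the order of the comparisons, camera with an estimated correlation called 1, 1 and 3 lists, fry 22, 27 and 23, and fry for change in either direction 31, 31 and 30. Neither fry test compares a list with other genes. With a strong change required in each comparison, 451 genes changed alike and 2 oppositely against 2D, 979 changed back and 18 further. Another 169 changed strongly between the 3D groups and not strongly in 3D_E against 2D, where they may still have been called with a smaller change. The 1000 most variable genes put 80.1% and 15.9% on the first components. Leaving out each library gave 1106 to 1525 genes lower in 3D_L than in 2D and 391 to 865 strongly lower in 3D_L than in 3D_E. It gave 42 to 268 genes in opposite directions and 479 to 870 called between the 3D groups and not in 3D_E against 2D. Lists called between the 3D groups numbered 6 to 11, and the correlation was 0.694 to 0.753. The median, mean and test differed in sign for 10 list results, 0 of them called. With the replicate number as a block (replicate block), 3669 and 3246, 1908 and 1428, and 2701 and 2580 genes were higher and lower and 12, 18 and 7 lists were called. Each gene's group mean was then subtracted and libraries of different groups were correlated. Libraries of the same number gave r of -0.404 to 0.182 and those of other numbers -0.365 to 0.400. Libraries of the same number thus did not correlate more highly than others, and the replicate numbers gave no sign of pairing the libraries across groups. Reads could not be recovered from FPKM without gene lengths, so voom was not run, and the depth that limits low genes is unknown.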

Other observations

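The tests of a mixture of cells and of different distances of the 3D_E libraries were chosen after the results were seen, and the others before. Members of the oxidative stress, fatty acid and glycolysis lists went both ways, and these lists were not called. The citrate lyase ACLY fell from 135 ± 7.29 in 2D to 59.6 ± 8.19 in 3D_E and 103 ± 6.76 in 3D_L, the elongase ELOVL5 from 108 ± 5.87 to 36.2 ± 4.80 and 65.1 ± 4.44, and the glycolytic enzyme PGAM1 from 1022 ± 50.2 to 585 ± 42.3 in 3D_E. NQO1, a quinone reductase, rose from 83.9 ± 5.04 in 2D to 273 ± 37.3 in 3D_E and 184 ± 9.53 in 3D_L. The peroxiredoxin PRDX6 rose from 109 ± 7.09 to 314 ± 18.7 and 290.2 ± 26.0 (limma, adjusted p = 7.40e-07 and 5.25e-06). HMOX1, which breaks down haem, stood at 116 ± 4.93 in 2D, 102 ± 35.9 in 3D_E and 274 ± 9.65 in 3D_L, and was higher in 3D_L than in both other groups. Malic enzyme ME1, a source of NADPH, rose from 0.177 ± 0.129 to 3.16 ± 0.953 and 2.85 ± 0.193, and the desaturase FADS2 from 14.0 ± 0.216 in 2D to 30.8 ± 2.21 in 3D_L. Lactate dehydrogenase LDHA stood at 1208 ± 99.9, 1396 ± 327 and 1985 ± 93.9 in the same order, and the growth factor VEGFA at 6.09 ± 1.03, 12.04 ± 1.26 and 11.3 ± 0.876.

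Mitosis and DNA replication genes were lower in 3D_E than in 2D. Scaling by size factors or TPM shifted the median of this comparison by -0.0109 and 0.0171, far less than the fall seen. Relative to the median of all genes, the mitosis and DNA replication lists lay at -2.373 and -1.724 as deposited. They lay at -2.374 and -1.725 with size factors, at -2.327 and -1.724 with quantile normalization and at -2.444 and -1.749 with TPM. A few genes taking most of the signal would change the other genes by -0.0428 on the log2 scale, from the share held by the 100 highest genes, far less than the fall seen. Fewer dividing cells in 3D_E may be the reason, as a hypothesis that these data do not test.

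On component 1, 3D_L lay between 2D and 3D_E, so it could be a mixture of 2D-like and 3D_E-like cells. Over members strongly changed in 3D_E with a 3D_L level between those groups, a mixture in 1 proportion would give all lists a like share of the way to 3D_E, and the lysosome list lay -0.0350 from the mitosis list, at 0.313 against 0.348, as a mixture would have it. Against 1 proportion for every list, 2 of 20 lists had quartiles apart from mitosis and lay over 0.15 from it in all 27 choices of libraries. They were actin by 0.350 (0.253 to 0.480) and ATF4 by 0.317 (0.234 to 0.435). These rest on only 7 and 8 members, against 31 for mitosis. Of the 11 actin members strongly changed in 3D_E, 63.6% lay between the groups and were used. The integrin (0.252), NRF2 (0.278), interferon (0.231), ribosome biogenesis (0.235), fatty acid (0.164) and inflammatory lists (0.156) lay over 0.15 from mitosis, but not in all choices. Genes strongly above or below both groups in 3D_L, such as HAS2 and IL8L2, numbered 91 against at most 1 in simulated unchanged groups. A mixture alone keeps every gene between its 2D and 3D_E levels, so these genes argue against a mixture without other changes, for the genes they cover. Their number fell short of the bound of more than 100 that was set, after the results were seen, for excluding a mixture. A mixture with some genes of its own and a state between the other groups cannot be told apart.

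The libraries of 3D_E lay further apart than those of the other groups, with GJA1 and CTSD among the genes that differed most between replicates 3 and 1. Different distances along the 2D to 3D_E change could give this, and the difference between replicates 3 and 1 correlated with the 3D_E minus 2D change at r = 0.364 across genes, between the bounds of below 0.3 set against it and at least 0.5 set for it. A bias for short transcripts or RNA quality could also give it, and the respiratory chain genes differed from the other genes by 0.264 and the ribosomal protein genes by 0.484, between the bounds of 0.25 and 0.5 for the smaller of these. In 3D_L, replicate 3 differed from replicates 1 and 2 by a median of 0.265 for ribosomal protein genes and 0.249 for respiratory chain genes. A difference of this kind was thus not confined to 3D_E. With 3 libraries these explanations cannot be told apart.

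In fits of only the groups compared, 1 of the 10 splits of the 6 libraries, the real split, gave as many changed genes as the labels did in each comparison, 6674 in 3D_E against 2D, 5783 in 3D_L against 2D and 4503 in 3D_L against 3D_E. The highest of the other splits gave 0, 0 and 0. With 10 splits the share cannot fall under 0.05.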
